A study of Mus musculus with 6 samples.

How the data were processed

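MicroRNA (miRNA) levels were measured in whole kidney of male C57BL/6 mice of 2 ages, 2 months (young, 3 arrays) and 20 months (aged, 3 arrays). C57BL/6 is a standard inbred laboratory strain. Per the labels' protocols, total RNA with its small RNA fraction was purified, and 100 ng was dephosphorylated and ligated to a Cy3-tagged nucleotide. Each preparation was hybridised to its own 1-colour Agilent miRNA array. The series design speaks of independent RNA preparations per group. The labels do not tie a preparation to an animal, so p-values measure the spread between preparations, which may be partly technical.

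Per the file headers, the arrays were of design 046065 and were read with Feature Extraction 11.5.1.1, with mm9 as the build of the design. The deposited spot values are fluorescence intensity per the file headers, already corrected for background by the scanner software and not scaled between arrays. The deposited flags, per the file headers, state for each spot whether it was well above background, an outlier or saturated. A table of values processed by the authors was also deposited on a log2 scale. It equalled log2 of the scanner software's total signal per miRNA less 1 constant per array, with a largest departure of 1e-05 over 1268 features. The direction and the scale of that table are therefore known, and the statistic behind the constant is not given in the sources used here. Its medians per array were -9.74, -9.21 and -9.21 in young kidney and -9.48, -10.10 and -9.20 in aged kidney, since most features were undetected.

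Each array held 52044 spots, of which 49880 were not controls. These belonged to 3105 probes for 1247 mouse miRNAs, with 1 to 4 probes per miRNA and 10 to 40 spots per probe. No spot was saturated (0 on each array). The processed intensity was averaged over the spots of a probe, leaving out outlier spots. It was divided by the array's 75th percentile over the 315 probes well above background on all 6 arrays, and summed over the probes of a miRNA. Values under a floor of -5.22 (log2) were set to it, and log2 was taken. The floor was the median over arrays of the lowest scaled signal of a probe well above background. A probe counted as well above background where over 50% of its kept spots carried that mark. Within a group, 43.2 to 74% of the probes differed between arrays by more than the noise between spots, where 5% would differ by that noise alone. This does not tell separate samples from repeat hybridisations of 1 RNA, and the arrays were counted as separate per the labels.

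The 193 miRNAs with a probe well above background on all 3 arrays of at least 1 group were tested. Aged and young values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the single term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are those of limma. A miRNA not well above background on every array of 1 group is given a lower bound. The bound sets the mean of the brighter group against, per array of the dimmer group, the highest of the array's lowest signal among probes well above background, the common floor and the miRNA's own signal. The common floor was added to the bound after a first bound for miR-551b-3p without it was seen to exceed the measured fold. Lists of miRNAs were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, over the 15 of 17 lists that had at least 3 tested members. The number of detected miRNAs was compared with an exact two-sided permutation test. Input was read with jsonlite 2.0.0 and with data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9.

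The groups, the tests, the lists, the alternatives and the rule for the miRNAs named in the text were fixed before the data were examined, apart from 2 alternatives named as later additions. The rule took the 8 largest rises and the 8 largest falls past the threshold with non-overlapping groups, and up to 3 members of each list with the smallest p. It further took miR-21a-5p, miR-34a-5p, miR-192-5p, miR-29b-3p, miR-200b-3p and miR-126-3p, and the 5 brightest miRNAs. It gave 59 miRNAs. Names are those of the array design without the species prefix. Newer list names were matched to the design's older names (miR-142a to miR-142, miR-126a to miR-126, miR-486a-3p to miR-486-3p and miR-486b-5p to miR-3107-5p) through RefSeq synonyms on GRCm38.p6, after the files had been opened. That assembly differs from the design's build, so no coordinates are given, and it served only for names and for which hairpins lie near each other.

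The procedure was tested on simulated data for the comparison of aged with young kidney, with 193 miRNAs and 40 simulations. It called 19.5% of planted differences of 0.3 (log2), 80.8% of those of 0.6 and 94.2% of those of 1.2, and 3.95% of its calls were false. In simulations with no difference, 1 of 40 gave any miRNA call and 2 gave any list. Differences of about 0.3 were thus mostly missed at 3 arrays per group. In the simulations miRNAs varied independently of each other and shared no array effect. The simulated rate of false lists therefore does not cover lists whose members vary together.

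All arrays came from 1 slide and 1 scan, so no fit with slide or scan as a term was run. The position on the slide was known: row 1 held the 3 young arrays and aged array 1, and row 2 held aged arrays 2 and 3. Alternatives covered background correction (normexp with an offset of 50 on the median spot and background signals, in place of the mean spot signal planned, which was not used here), scaling between arrays, the detection filter, the floor, the summary over probes, outlier spots, the variance model, the authors' values, a replicate block, slide row as a block, thresholds, set tests and leaving out each array. The detection definition was varied too.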

Results

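The series compared the miRNA content of mouse kidney between youth and old age. Total RNA of 3 preparations from 2-month-old males and 3 from 20-month-old males was hybridised to arrays that carry probes for 1247 mouse miRNAs. In young kidney 209, 193 and 200 miRNAs were well above background, and in aged kidney 201, 206 and 177. The 75th percentile of the probes detected throughout ranged 1.75-fold between arrays, from 1171 to 2054 intensity units. The number of arrays limits the precision. Across the tested miRNAs, young arrays correlated with each other at 0.998 and aged arrays at 0.972 to 0.989. Aged array 1 correlated more closely with the young arrays, which share its slide row (0.991 to 0.993), than with aged arrays 2 and 3 (0.983 and 0.972).

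In aged kidney 8 miRNAs rose, and the miR-29 family and miR-34a-5p led those with signal in both groups. The family, known to repress collagens and other matrix transcripts, rose in its 3 mature forms: miR-29b-3p by 0.68 ± 0.07 (log2 difference ± SE, n = 3 per group, 1.6-fold), miR-29a-3p by 0.63 ± 0.07 (1.55-fold) and miR-29c-3p by 0.56 ± 0.08 (1.48-fold). miR-34a-5p, a transcriptional target of p53, rose by 0.71 ± 0.12 (1.63-fold). miR-199a-3p and miR-199a-5p, the opposite arms of miR-199a, which is abundant in mesenchymal cells, rose by 0.41 ± 0.09 and 0.34 ± 0.07. miR-124-3p, known as a neuronal miRNA, was not well above background on any young array. With the main processing it was at least 2.45-fold higher in aged kidney.

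The limma adjusted p was 0.00399 for miR-29b-3p, 0.00495 for miR-29a-3p and 0.0134 for miR-29c-3p. The opposite arm of the last, miR-29c-5p, rose by 0.61 ± 0.09 (limma adjusted p = 0.0136). For miR-34a-5p the limma adjusted p was 0.0235, for miR-199a-5p 0.0258 and for miR-199a-3p 0.0391. miR-124-3p had a limma adjusted p of 8.63e-05, with its young values at the floor of -5.22 and an aged mean of -3.85. All its young values being the floor, their SD was 0, and this p-value measures no spread in young kidney. Over 17 alternatives that kept all arrays, the difference of miR-124-3p ranged from 0.51 to 7.98. Its call was lost in 1 of them (limma adjusted p = 0.106). Every aged array lay above every young array for each of these 8 miRNAs. The mature miR-29 forms are close in sequence, so signal on one probe can come from another member.

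In aged kidney 7 miRNAs fell. miR-455-3p fell by 0.88 ± 0.15 (log2, n = 3 per group, 1.83-fold) and its opposite arm miR-455-5p fell by 0.80 ± 0.10 (1.75-fold). miR-450a-5p and miR-503-5p, which are encoded in 1 cluster on the X chromosome, fell by 0.59 ± 0.11 and 0.43 ± 0.09. miR-181c-5p fell by 0.49 ± 0.09, and miR-141-3p, a member of the epithelial miR-200 family, fell by 0.38 ± 0.08. miR-551b-3p was not well above background on any aged array. With the main processing it was at least 2.71-fold lower there than in young kidney.

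The limma adjusted p was 8.63e-05 for miR-551b-3p, with a young mean of -3.68 and an aged mean of -5.18. It was 0.00705 for miR-455-5p, 0.0235 for miR-455-3p, 0.0258 for miR-450a-5p and miR-181c-5p, 0.032 for miR-503-5p and 0.0415 for miR-141-3p by limma. Every aged array lay below every young array for each of these 7 miRNAs. miR-551b-3p lay at the floor on aged arrays 2 and 3, so its p-value rests partly on the floor and not on measured spread. Over 17 alternatives that kept all arrays its difference ranged from -3.65 to -0.53. Its call was lost in 2 of them (limma adjusted p up to 0.304). miR-455-5p, miR-450a-5p and miR-503-5p were well above background on 1 of the 3 aged arrays, so their aged levels lay near the detection limit. The difference of miR-141-3p changed sign, to 0.03, with the 75th percentile taken over all probes, a scaling that raised the median difference of all tested miRNAs by 0.41.

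**Figure D1:**
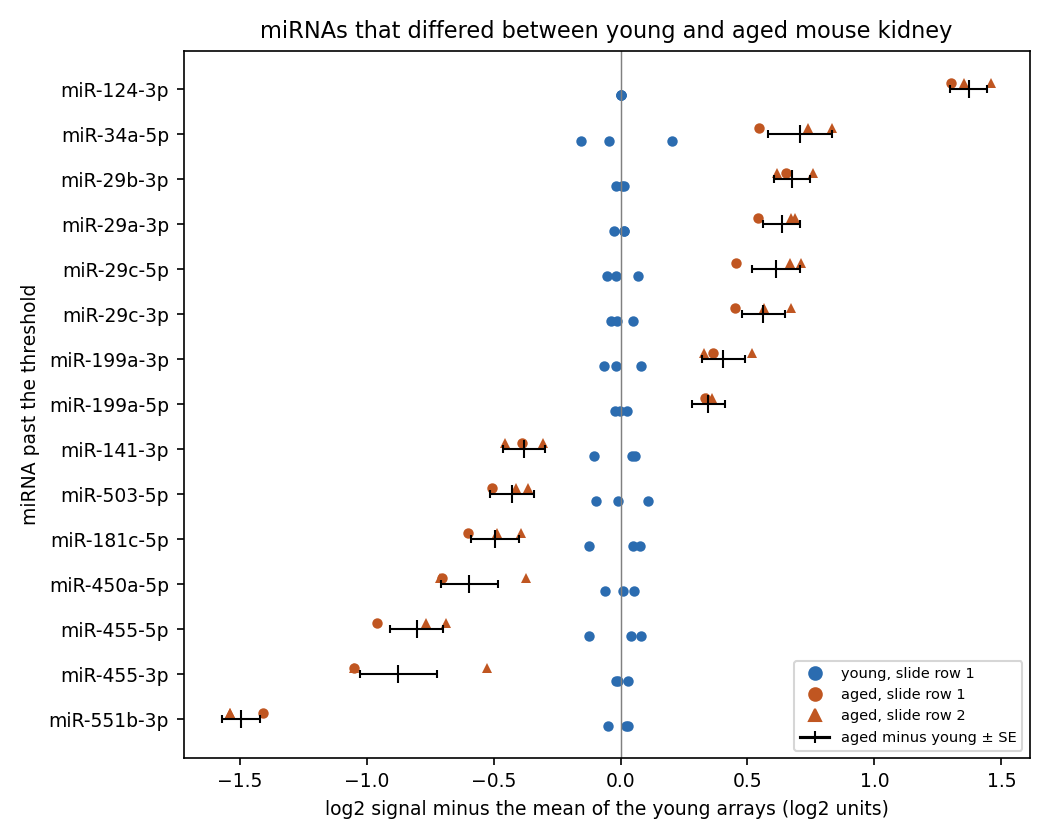
Log2 signal of the 15 miRNAs past the threshold on each array, relative to the mean of the young arrays (horizontal axis, log2 units). Points are arrays, coloured by age and shaped by slide row, and black bars are the aged minus young difference ± SE. Aged and young points do not overlap for any of the 15. The outermost, miR-124-3p drawn at 1.37 and miR-551b-3p at -1.49, were not well above background in 1 group. Their drawn sizes depend on the floor, and their bounds with the main processing are at least 2.45-fold higher and 2.71-fold lower. miR-141-3p changes sign to 0.03 with the 75th percentile over all probes.

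Of the 193 miRNAs tested, 15 passed the threshold and 49 had an unadjusted p under 0.05. The median difference of all tested miRNAs was -0.08. Groups did not overlap for 20 miRNAs with higher and 39 with lower aged values, 30.6% of those tested where chance gives 10% on average. The miRNAs of an array share its scaling and its place on the slide. They are therefore not independent of each other, and the excess over 10% was not tested. With slide row as a block, miR-124-3p and miR-29b-3p remained higher and miR-551b-3p, miR-455-5p and miR-455-3p remained lower past the threshold (2 higher and 3 lower). In that comparison the age difference rests on aged array 1, the single aged array in the row of the young ones. Its negative controls had a mean of 6.85 and an SD of 133, against means of 3.04 to 4.21 and SDs of 6.85 to 9.66 on the other 5 arrays. Without 1 of its 1000 control spots, at 4191, the mean was 2.66 and the SD 6.19. Against the young mean it stood at 0.65 for miR-29b-3p, 0.54 for miR-29a-3p, 0.45 for miR-29c-3p, 0.55 for miR-34a-5p and -1.05 for miR-455-3p. With aged arrays 2 and 3 left out, an alternative added after the data were seen, 11 miRNAs were higher and 10 lower, 12 of them among the 15, but the spread there came from the young arrays alone and the single aged array was assumed to vary like them.

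The balance of directions depended on the scaling. Against 8 higher and 7 lower, quantile normalization gave 19 and 2, the median over detected probes 18 and 3, and the authors' processed values 10 and 0 (29 and 10 at an unadjusted p under 0.05 by limma). Scaling moved the median of all tested miRNAs by 0.41 with the 75th percentile over all probes, 0.20 without scaling, 0.14 with the median and 0.11 in the authors' values. With normexp background correction miR-29a-3p, miR-29b-3p, miR-29c-3p and miR-34a-5p were higher and 0 miRNAs lower (18 at an unadjusted p under 0.05 by limma). Counts moved by over 1.5 times without young array 1 (4 higher, 2 lower), young array 2 (3 and 2), young array 3 (6 and 2), aged array 1 (12 and 27) or aged array 2 (5 and 4). miR-551b-3p, miR-124-3p, miR-29b-3p, miR-29a-3p and miR-455-5p stayed past the threshold whichever array was left out. The calls of miR-551b-3p and miR-124-3p rest partly on values at the floor. Of these 6 fits miR-29c-3p and miR-29c-5p each passed in 4 and miR-34a-5p in 2 (limma adjusted p up to 0.0925), and miR-199a-5p and miR-199a-3p each passed in 1. Among the falls, miR-455-3p, miR-450a-5p and miR-181c-5p each passed in 2, and miR-503-5p and miR-141-3p each in 1.

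Among the miRNA lists, the miR-29 family and the renal injury and fibrosis list passed the camera test at the preset correlation and not at an estimated one. All 3 members of the miR-29 family rose, with a median difference of 0.63 (camera adjusted p = 0.000118, and 0.302 with an estimated correlation). Of the 7 tested members of the injury and fibrosis list, miR-199a-3p and miR-199a-5p rose, and 3 rose when adjusted over the list alone, with miR-214-3p at 0.30 ± 0.09 added. All 7 had positive differences with a median of 0.30 (camera adjusted p = 0.00115, and 0.302 with an estimated correlation). Of these 7, miR-199a-3p, miR-199a-5p and miR-214-3p also stand in the stromal list, and miR-146a-5p and miR-155-5p in the leukocyte list. miR-21a-5p, a miRNA induced in renal injury, stood at 0.08 ± 0.09 (limma adjusted p = 0.586), and at -0.08 under quantile normalization. Of the other 9 divisions of the 6 arrays, 7 gave as many lists at the preset correlation. The fibrosis list had an adjusted p of 0.0531 with the 75th percentile over all probes, and its median was 0.07 with normexp (camera adjusted p = 0.0311, in a range of 0.000432 to 0.0531 over 24 alternatives at the preset correlation and of 0.2 to 0.887 at an estimated one).

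Of the 5 tested members of the senescence and p53 list, miR-34a-5p and miR-29a-3p rose, also when adjusted over the list alone, and miR-22-5p stood at -0.16 ± 0.08 (-0.11 without aged array 1). The list's median was -0.02 and its mean 0.22, of opposite sign, and the median was positive under 4 other scalings and in the authors' values (camera adjusted p = 0.145, and 0.0404 with normexp, in a range of 0.0404 to 0.381 over the alternatives, and 0.378 with normexp at an estimated correlation). In the smooth muscle and stromal list 2 of 9 tested members rose, both arms of miR-199a. Adjusted over the list alone 4 rose, with miR-199b-5p at 0.33 ± 0.08 and miR-214-3p added, and 1 fell, miR-143-3p at -0.27 ± 0.09, which was named after its value was seen. Its median of -0.01 and mean of 0.06 differed in sign, and the median was positive under other scalings (camera adjusted p = 0.208).

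Markers of blood cells moved apart without passing the threshold over all miRNAs. miR-223-3p, known from neutrophils and other myeloid cells, stood 0.55 ± 0.13 higher in aged kidney (limma adjusted p = 0.051) on all 3 aged arrays. miR-142-3p, made in cells of the blood lineage, stood at 0.46 ± 0.17 and miR-146a-5p at 0.25 ± 0.09, both named after their values were seen. miR-181a-5p and miR-181b-5p, also in the leukocyte list, stood at -0.47 ± 0.12 (limma adjusted p = 0.0528) and -0.52 ± 0.14 (limma adjusted p = 0.0791). miR-223-3p passed the threshold without young array 3 (0.67) or aged array 1 (0.52), and miR-181a-5p and miR-181b-5p passed without aged array 3 (-0.57 and -0.66). Of the 8 tested leukocyte miRNAs 0 passed over all miRNAs by limma, 5 had an unadjusted p under 0.05, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.145). The list's median was 0.28, and 0.03 with normexp, where none of the leukocyte miRNAs passed over all miRNAs.

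The 3 tested erythroid miRNAs were all lower in aged kidney. miR-451a stood at -0.34 ± 0.09 and miR-3107-5p at -0.56 ± 0.14 (limma adjusted p = 0.0528 for both), and miR-144-3p at -0.73 ± 0.25 (limma adjusted p = 0.124). Without aged array 3 miR-144-3p stood at -0.42 ± 0.09 and passed the threshold, and without aged array 1 all 3 passed, at -0.38, -0.66 and -0.90. Over all miRNAs 0 passed by limma, 3 had an unadjusted p under 0.05, and adjusted over the list alone all 3 fell. The list's median was -0.56 (camera adjusted p = 0.14), and it passed under quantile normalization (0.0241), the median over detected probes (0.0367) and the authors' values (0.0355), in a range of 1.85e-07 to 0.251 over the alternatives at the preset correlation. With an estimated correlation its camera adjusted p was 0.544, and 0.0997 to 0.887 over the alternatives. The difference of miR-451a was 0.07 with the 75th percentile over all probes.

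Among epithelial and kidney-enriched miRNAs, the miR-200 family had 1 fall in 5 tested members, miR-141-3p, and 2 falls adjusted over the list alone, with miR-200c-3p at -0.33 ± 0.11 added. miR-200a-3p stood at -0.16 ± 0.08 and miR-200b-3p at -0.18 ± 0.09 (limma adjusted p = 0.273). The family's median of -0.18 turned positive with the 75th percentile over all probes (0.24) and without scaling (0.03) (camera adjusted p = 0.145, and 0.0298 with slide row as a block, in a range of 1.47e-09 to 0.603 over the alternatives; with an estimated correlation 0.703, and 0.133 to 0.887 over the alternatives). Of the 7 tested kidney-enriched miRNAs 0 passed by limma, over all miRNAs or over the list alone, and 1 had an unadjusted p under 0.05. miR-194-5p stood at 0.28 ± 0.09 (limma adjusted p = 0.104; 0.36 and past the threshold without aged array 1), miR-192-5p at 0.14 ± 0.11, miR-10b-5p at -0.16 ± 0.09 and miR-196b-5p at -0.19 ± 0.11 (the last 2 at -0.11 without young array 3).

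The let-7 family, the miR-30 family, the miR-17 cluster with its paralogous clusters and the endothelial list showed 0 changed members by limma, over all miRNAs or adjusted over each list alone. In the let-7 family all 9 members were tested, with let-7b-5p at 0.19 ± 0.13 (0.05 without aged array 3), let-7c-5p at 0.14 ± 0.11 and let-7i-5p at -0.14 ± 0.10. In the miR-30 family miR-30b-5p stood at -0.15 ± 0.08, miR-30d-5p at -0.14 ± 0.09 and miR-30c-5p at 0.09 ± 0.09. Of the 9 tested miRNAs of the miR-17 and paralogous clusters, miR-19a-3p stood at -0.26 ± 0.08 (limma adjusted p = 0.0843), the single member of these lists with an unadjusted p under 0.05, with miR-19b-3p at -0.13 ± 0.08 and miR-106b-5p at -0.12 ± 0.08. The endothelial miRNA miR-126-3p stood at 0.08 ± 0.08 (limma adjusted p = 0.519), miR-23a-3p at 0.11 ± 0.08 and miR-27a-3p at -0.04 ± 0.08. The medians were 0.04 for let-7, -0.03 for the miR-17 clusters, -0.03 for miR-30 and 0.05 for endothelial miRNAs (camera adjusted p = 0.332, 0.733, 0.976 and 0.332). Without a detection filter the miR-17 and miR-30 lists passed at the preset correlation (camera adjusted p = 7.34e-05 and 0.0171). At an estimated correlation neither did (camera adjusted p = 0.327 for both). The let-7 median was positive under all 4 other scalings and -0.10 with slide row as a block. The signs of the other 3 medians depended on the scaling, with all 3 positive when the 75th percentile was taken over all probes, and the endothelial one at -0.02 under quantile normalization.

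**Figure D2:**
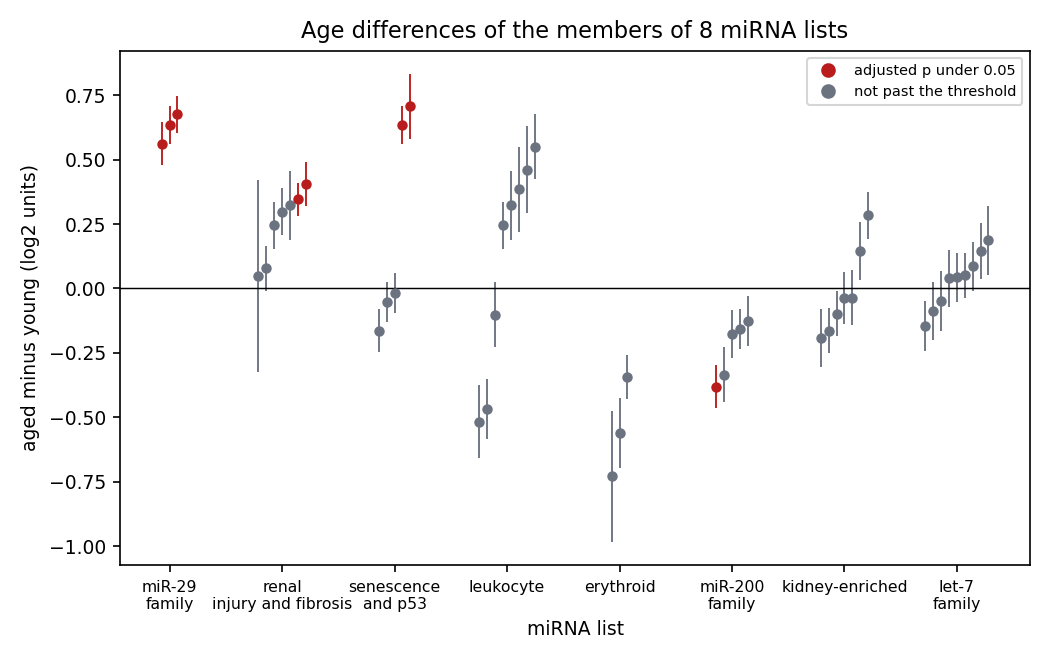
Aged minus young log2 difference (vertical axis, log2 units) of each tested member of 8 miRNA lists. Points are miRNAs with bars of ± SE, red where the limma adjusted p is under 0.05; the 3 miR-29 members lie between 0.56 and 0.68, all 3 erythroid members lie below 0 (miR-451a is at 0.07 with the 75th percentile over all probes), and let-7 members lie on both sides of 0.

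In the list of miRNAs typical of other organs miR-124-3p rose, the 1 change in 3 tested members and also adjusted over the list alone, while miR-128-3p stood at -0.04 ± 0.11 and miR-202-3p at -0.17 ± 0.23 (0.03 without aged array 2). The muscle miRNA miR-1a-3p was detected on 2 young and 2 aged arrays and was not tested. The list's median was -0.04 and its mean 0.39, of opposite sign, and the median was positive under other scalings (camera adjusted p = 0.145). The hypoxia-induced miR-210-3p stood at -0.39 ± 0.17 (limma adjusted p = 0.194), at -0.26 without young array 3 and at 0.02 with the 75th percentile over all probes. Of the Dlk1-Dio3 imprinted locus miR-494-3p was the 1 member tested, at -0.36 ± 0.18, at -0.15 without aged array 2 and at 0.06 with the 75th percentile over all probes.

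Repeat-like miRNAs listed as the intronic cluster of Sfmbt2 were low on aged arrays 2 and 3 and not on aged array 1. The pattern was far more frequent in this list than outside it, but was not confined to it. It was counted as 2-fold or more below the young mean on both arrays, and not on aged array 1. Of the 6 tested members of the list 4 showed it, and of all other miRNAs among the 193 tested, 7 did. These 7 were miR-1187, miR-1196-5p, miR-3082-5p, miR-32-3p, miR-468-3p, miR-6348 and miR-672-5p, counted after the data were seen. Whether they resemble the list in sequence was not examined. Between ages miR-466h-5p stood at -1.35 ± 0.52, miR-466m-5p at -0.89 ± 0.38 and miR-669e-5p at -0.77 ± 0.33. These sizes and SEs were set by the floor, at which the last 2 lay on aged arrays 2 and 3 and the first on aged array 3, and with a smaller floor they were -1.64, -1.69 and -1.63. Of the 6 tested members 0 passed by limma, over all miRNAs or over the list alone, and 1 had an unadjusted p under 0.05. The list's median relative to the young mean was 0.01 on aged array 1, and -1.25 and -1.50 on aged arrays 2 and 3, where 3 and 4 of the 6 members lay at the floor, so the fall there is at least as large. The list had a camera adjusted p of 0.145 between ages, and 0.731 with an estimated correlation, which was 0.932 among its members. At the preset correlation of 0.01 it passed with the 75th percentile over all probes, without scaling, with the median over detected probes, under quantile normalization and in the authors' values, where an estimated correlation gave a camera adjusted p of 0.641 to 0.795. Without aged array 1, miR-466h-5p, miR-466m-5p and miR-669e-5p and the list at the preset correlation also passed. Those calls rest on values at the floor for miR-466m-5p and miR-669e-5p, and partly so for miR-466h-5p and the list. Of the members above the floor on both arrays, miR-669n, named after its value was seen, stood at -1.63 and -2.91 against the young mean. The list was drawn up by name, its tested members being miR-466 and miR-669 miRNAs, and their place in the genome was not checked. The sequences of its members were not compared. Signal on the probe of one repeat-like member may come from another, so their single levels are uncertain.

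**Figure D3:**
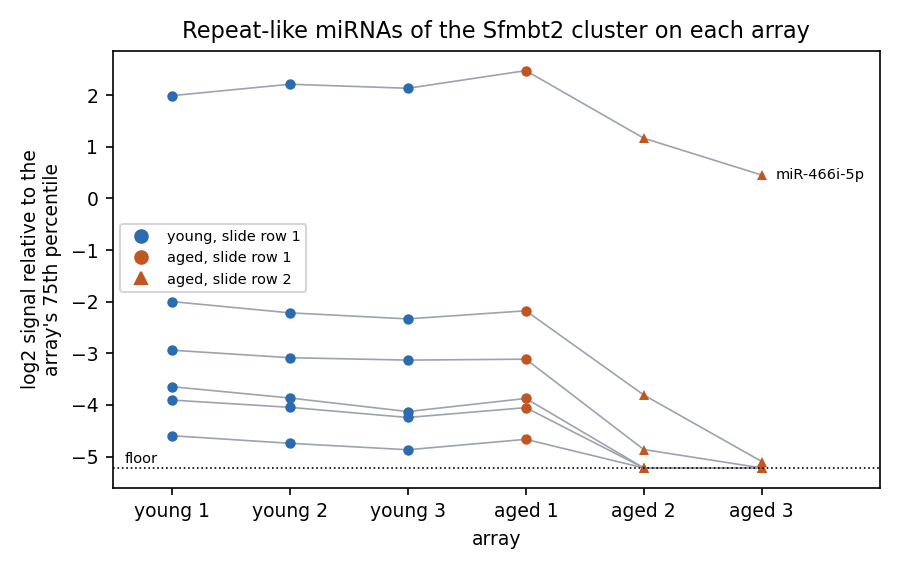
Log2 signal relative to the array's 75th percentile (vertical axis, log2) of the 6 tested miRNAs of the Sfmbt2 list on each of the 6 arrays. Points are arrays, coloured by age and shaped by slide row, each grey line joins the values of 1 miRNA, and the dotted line is the floor at -5.22; the list's median on aged array 1 lies 0.01 from the young mean, while aged arrays 2 and 3 lie at -1.25 and -1.50.

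Of the 12 tested GC-rich or fragment-like miRNAs 0 passed by limma, and 0 had an unadjusted p under 0.05. miR-1187 stood at -0.91 ± 0.52, miR-3470a at -0.54 ± 0.34 and miR-5105 at -0.25 ± 0.16. The list's median was -0.28, and 0.14 with the 75th percentile over all probes (camera adjusted p = 0.332). It was 0.03, -0.74 and -0.02 on aged arrays 1, 2 and 3 against the young mean, and the difference was -0.07 without aged array 2. Without aged array 2 miR-3470a and miR-5105 stood at -0.19 and -0.07, and without aged array 3 miR-1187 stood at -0.40. Without aged array 1, miR-1187 and miR-3470a passed the threshold, at -1.51 and -0.89. The 5 brightest miRNAs were miR-6366, miR-3963, miR-5100, let-7a-5p and let-7f-5p, with differences of -0.09 ± 0.14, 0.00 ± 0.16, -0.03 ± 0.13, 0.09 ± 0.10 and 0.05 ± 0.09.

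The number of detected miRNAs was 201 ± 8.02 in young and 195 ± 15.5 in aged kidney (SD, n = 3 each). The difference of -6 was within the spread between arrays (exact two-sided permutation p = 0.7, where 0.1 is the smallest that 3 against 3 arrays allow). It was 2.83 without aged array 3, on which 177 miRNAs were detected. miR-124-3p was the 1 miRNA detected on all aged and no young arrays, and miR-551b-3p the 1 with the opposite pattern.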

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

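Leaving out aged arrays 2 and 3, a robust prior in limma and the rule for sign changes were chosen after the data were seen. A sign change was counted as a reversal only where the miRNA passed the threshold in either setting. The first version of the rule counted every one, 94 over 35 of the 59 named miRNAs (22 with the 75th percentile over all probes, 15 without scaling). Under the later rule 1 was left, miR-141-3p at 0.031 with the 75th percentile over all probes, a scaling that raised the median of all miRNAs by 0.41.

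Against 8 higher, 7 lower and 2 lists, the counts of higher and lower miRNAs were 4 and 0 with normexp, 1 and 1 without scaling, 4 and 2 without a detection filter (7 lists, with more miRNAs in the test), 2 and 3 with slide row as a block, 1 and 1 at 2-fold and 14 and 20 at an adjusted p under 0.10. Quantile normalization gave 19 and 2 (4 lists), the median over detected probes 18 and 3 (4 lists) and the authors' values 10 and 0 (4 lists). The scanner software's total signal gave 2 lower. The lists numbered 0 with an estimated correlation in camera (2 at an unadjusted p under 0.05) and 4 with fry, which does not compare a list with other miRNAs. Where the construction does not show it, the cause was not tested. Counts stayed within 1.5 times with the 75th percentile over all probes (though 7 of the 15 miRNAs were shared), detection on all 6 arrays, a smaller floor, other summaries over probes, outlier spots kept, a trend, array weights (which stopped before convergence), and the robust prior. They did so too with aged arrays 2 and 3 left out, where the spread came from the young arrays alone. At the preset correlation the miR-29 list passed in 24 of 24 alternatives and the fibrosis list in 23, and at an estimated one each in 0 of 24.

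Leaving out 1 array gave 3 to 12 higher, 2 to 27 lower and 2 to 3 lists, and a difference in detected miRNAs of -11.7 to 2.83. The replicate block gave 2 higher and 1 lower (2 lists). Deviations of same-numbered arrays correlated with r of 0.12, -0.58 and 0.31. These few values show no common pairing by number but cannot exclude one, and the series design names none. Slide and scan as a block were not run, with 1 of each. Low signal over background limits miR-455-5p, miR-450a-5p and miR-503-5p, and miR-124-3p and miR-551b-3p have bounds only. The floor sets values of miR-466m-5p and miR-669e-5p on aged arrays 2 and 3, and of miR-466h-5p on aged array 3.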

Other observations

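Apart from the divisions of the arrays and the opposite arms of miR-29a and miR-29b, the tests in this part were chosen after the results they bear on had been seen. Arms of 1 hairpin and neighbouring hairpins had similar age differences. Both arms of miR-378a stood lower in aged kidney, at -0.37 and -0.31, and both arms of miR-1839 higher, at 0.29 and 0.24, none past the threshold. These miRNAs and the pairs named below, apart from miR-503-5p, were picked after their values were seen. Differences were permuted among the 154 tested miRNAs mapped to 1 hairpin, leaving out the Sfmbt2 list. In 11 pairs of arms the median gap was 0.06, against 0.26 when permuted (one-sided permutation p = 0.0013, 10000 permutations). Shared transcription of a hairpin may account for it, but this was not tested apart from variation that miRNAs share on an array. In 28 pairs of miRNAs from hairpins within 10 kb the median gap was 0.09, against 0.26 (one-sided permutation p = 3e-04). Examples are miR-143-3p and miR-145a-5p at -0.27 and -0.25, and miR-322-5p and miR-503-5p at -0.31 and -0.43. Counterexamples are miR-188-5p at -0.60 beside miR-532-5p at 0.06 and, among arms, miR-193a-3p at -0.07 and miR-193a-5p at 0.31. Some neighbours resemble each other in sequence, so cross-hybridisation stays open for them. Both permutation p-values come from exchanging miRNAs measured on the same arrays, and they measure no spread between arrays.

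The count of 15 miRNAs past the threshold was set against the other 9 divisions of the 6 arrays into 3 and 3. The real division was the 1 of 10 with as many, and the highest other gave 0 by limma (19 at an unadjusted p under 0.05, against 49). For the lists, 8 of the 10 divisions, the real one included, gave as many as the real 2, and the highest other gave 3. With 10 divisions a share under 0.05 cannot be reached.

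The rise of the miR-29 family was weighed against slide row, scaling and cross-hybridisation. Under quantile normalization, the scaling alternative that is not 1 constant per array, the family median less that of all tested miRNAs was 0.51, which argues against scaling as the whole cause. The opposite arm miR-29c-5p, of another sequence, rose by 0.61, which argues against cross-hybridisation as the whole cause for miR-29c-3p. For miR-29a-3p and miR-29b-3p it stays open, since 0 of their opposite arms were well above background on all arrays, and age stays open as untested. Slide row stays open, since aged array 1, at a family median 0.54 above the young mean, is a single array, and with slide row as a block, where SEs were larger, miR-29b-3p passed at 0.65 ± 0.12 but miR-29a-3p and miR-29c-3p, at 0.54 ± 0.11 and 0.45 ± 0.12, did not.

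The low miRNAs of the Sfmbt2 list on aged arrays 2 and 3 were weighed against a loss of signal, slide row and age. On the same scale and against aged array 1, 4 spike-in controls had medians of -0.70 and -0.13 on those arrays. The members of the list had -1.33 and -1.69, at least 0.63 further down (-0.632 on aged array 2). The SE of that value, 0.18, was taken over controls and members on 1 pair of arrays and measures no spread between arrays. Before scaling, the 4 controls on aged arrays 2 and 3 together differed from aged array 1 by -0.07 to 0.20. The -0.70 reflects the higher 75th percentile of aged array 2 (2054, against 1171 on aged array 1). The controls argue against a loss of signal over the whole array as the whole cause. The list's median was at least 1.26 lower on aged arrays 2 and 3 than on aged array 1 (-1.26 for the nearer array). Slide row and a difference between preparations cannot be told apart, since row 2 held these 2 arrays alone. An effect of age shared by the group stays open too, as aged array 1, at 0.01 from the young mean, is a single array.

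Less residual blood in aged kidney may lower erythroid miRNAs, whose median was -0.56, and nothing measured here tests another origin for them. For the higher miR-223-3p, more myeloid cells in the aged tissue is a hypothesis that these data do not test. Aged array 1 stood 0.60 above the young mean for miR-223-3p, a single array, so slide row stays open.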
